A study of Mus musculus with 12 samples.

How the data were processed

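The samples were single-cell libraries from CD45+ cells of BALB/c mammary tumours, made with a 5′ droplet kit and, for the receptor libraries, a mouse T cell V(D)J enrichment kit, per the labels' protocols. Per the submitters' processing notes, the authors used Cell Ranger 3.0.2 and the mouse genome builds mm10 and GRCm38, which are names of the same assembly. The deposited table lists assembled receptor contigs with their read count and their UMI count, whole numbers that are not normalized, with the cell call, chain, V and J gene, CDR3, productive status and clonotype identifier. The contig calls, cell calls and gene names were taken as deposited.

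The table held 11 library names, of which 6 were tied to a sample by a number matching that sample's title. The other 5 matched no label and were not used. The expression matrices were not used here. By the labels, 4 of the 6 libraries were treated, 1 was untreated, and 1 (PBS2) carried conflicting labels, treated in its receptor record and untreated in the record of its paired expression library. The tags CTX, CSF1R, Combined and PBS are names in the table, and the labels do not define them. The 311634692 reads and 213458 UMIs of the 6 libraries fell on 39266 contigs.

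Contigs in called cells and marked productive were used, with no further minimum. Each cell took the TRB contig with the most UMIs, and a clone was the set of cells in 1 library with the same TRBV gene and CDR3 nucleotide sequence. TRB alone was used because a missing TRA contig would otherwise split a clone. Doublets were kept, and leaving out cells with 2 or more productive TRB or 3 or more productive TRA contigs was tried as an alternative. Because the number of clones depends on the number of cells, each library was drawn down to the 192 TRB cells of the smallest, and values are means of 1000 draws with a fixed seed. Shares of 1 library carry exact Clopper-Pearson 95% intervals, which cover counting error only. For a count of 0 the limit given is 3 counts of the total.

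Treated and untreated libraries were compared with a two-sided exact permutation test of the difference of means. Differences within libraries were tested with a two-sided exact sign-flip permutation over the 6 libraries. Their smallest possible p is 0.03125, where the plan made before the data were examined had foreseen 4 libraries. Odds ratios had 0.5 added to each count and stood beside Fisher's exact test per library. Rank correlations used 100000 permutations within libraries. Adjusted p-values are by Benjamini-Hochberg. Distinct rearrangements were counted once per library by V gene, J gene and CDR3 nucleotide sequence, or by contig length where no CDR3 was called. For pairs of TRA contigs in a cell, the 2 contigs with the most UMIs were used, and pairs with the same V and J gene were left out.

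Apart from TRBV23 and the genes of recurrent receptors, which were chosen after the values were seen, the genes named were fixed by a rule before the data were examined. They are TRBV and TRBJ genes used by at least 5% of clones on average, the 10 TRAV and 5 TRAJ genes with the largest mean share, the genes of the superantigen, NKT, MAIT and TRBV13 lists, and the 3 largest TRB clones of each library. Ties in clone size were broken by total TRB UMIs. Positions of V and J genes came from a RefSeq gene table of assembly GRCm38.p6, in which all 105 TRAV and TRBV names matched. That assembly is from another strain than BALB/c.

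Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The functions were tested on simulated data. In a simulated library of 400 cells in 274 clones, with cells missing their TRA and others with an extra TRB, the expanded share of 40% was recovered as 40% and the clones as 274. The extra TRB always had fewer UMIs than the true TRB, so the rule of most UMIs could not fail there. Drawing down gave 79.6 clones where 79.5 were known. Of 1000 sets of 6 null values, a share of 0.029 passed 0.05 in the sign-flip test, where 0.03125 was known. A rank correlation of 0.483 in the simulated population was 0.452 in 200 cells drawn from it. The search for recurrent receptors found 10 of 10 planted pairs among 820 simulated clones. The planted pairs had identical amino acid sequences on both chains, so near matches were not tested.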

Results

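The series profiled CD45+ immune cells from mammary tumours of BALB/c mice. CD45 is a surface phosphatase carried by leukocytes, and sorting on it enriches immune cells from a tumour. The treatment protocol named in the labels is a 3-week course of cyclophosphamide, an alkylating chemotherapy, and pexidartinib, an inhibitor of the CSF1 receptor on which macrophages depend. Of the 12 samples, 8 were expression libraries, 4 untreated and 4 treated, and 4 were T cell receptor libraries, all labelled treated. The expression matrices were not analysed here. The receptor table held called contigs of the alpha chain (TRA) and beta chain (TRB) of single T cells, so each cell carried its own record of V gene, J gene and CDR3, the loop that contacts antigen.

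The table named 6 libraries that could be tied to a sample of the series, and they are called here by the table's own names. CTX, Combined and CTX2 were receptor replicates 1, 3 and 4 of the treated group. CSF1R was tied to treated expression replicate 1 and PBS1 to untreated expression replicate 3, through the expression library number that the table gives for each. The number given for CSF1R also begins the title of treated expression replicate 2, so its tie holds for the group and not for a single replicate. PBS2, receptor replicate 2, was labelled treated, while its table tag was PBS and its paired expression library was labelled untreated. PBS2 was therefore left out of the comparison of treated with untreated libraries, and its values are given beside it. The labels do not say which library came from which mouse, so p-values over libraries measure the spread between libraries only.

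The 6 libraries held 245 (PBS1), 552 (PBS2), 986 (CSF1R), 773 (CTX), 1333 (CTX2) and 7629 (Combined) called cells, 11518 in all. Reads per library ran from 31178451 in CTX to 83903661 in CSF1R, and molecules counted by unique molecular identifier (UMI) from 6807 in PBS1 to 121305 in Combined. Each UMI was read 625 times in Combined and 6194 times in CSF1R, so molecules and not reads limited the depth. The median TRB contig rested on 5 UMIs in CSF1R and on 16 in CTX2, and the median TRA contig on 3 UMIs in CSF1R and in Combined and on 7 in CTX2.

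Most called cells carried a complete alpha-beta receptor. Both a productive TRA and a productive TRB contig were found in 70.0% ± 6.83 of cells in the treated libraries (SD, n = 4), in 70.6% in PBS1 and in 68.3% in PBS2. CTX had the lowest share, 60.0% (exact 95% interval 56.5 to 63.5), and Combined the highest, 75.1% (74.1 to 76.0). A productive TRB was found in 68.8% of cells in CTX and in 94.2% in Combined. More than 1 productive TRB, a sign of doublets or of free receptor RNA, was seen in 4.79% of TRB cells in CTX2 and in 23.7% in CTX. Counting high-confidence contigs alone, these shares were 2.76% and 4.51%. Contigs of other receptors were rare in cells: 10 immunoglobulin contigs, a marker of the B lineage, and 2 gamma or delta chain contigs were found in the 6 libraries together. The libraries were enriched for T cell receptor sequences, so these counts do not measure the B lineage or gamma-delta T cells of the tumours.

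T cells in these tumours ranged from almost no clonal expansion to a repertoire in which most cells had a sister cell. A clone was defined as the cells of 1 library with the same TRBV gene and the same TRB CDR3 nucleotide sequence. In CTX2, 60.6% of TRB cells belonged to clones of 2 or more cells (exact 95% interval 57.7 to 63.6), and 14 clones of 10 or more cells held 50.0% of all TRB cells. In CTX the expanded share was 35.2% (31.1 to 39.4), in PBS1 37.5% (30.6 to 44.8) and in PBS2 16.4% (13.1 to 20.3). CSF1R and Combined held almost only single cells, with expanded shares of 4.16% (2.93 to 5.71) and 1.47% (1.21 to 1.78), and neither had a clone of 10 cells. Both shares depended on the definition of a clone: they were 1.71% and 0.471% with TRA and TRB together, 2.05% and 0.465% by deposited clonotype and 1.85% and 0.306% with clones of 3 or more cells, and Combined reached 4.65% by TRB amino acid sequence. Other shares also left their intervals. CTX fell to 28.6% without possible doublets and to 27.6% with clones of 3 or more cells. CTX2 fell to 56.3% by deposited clonotype and to 55.3% with clones of 3 or more cells. PBS1 fell to 30.4% by deposited clonotype, and PBS2 stayed within its interval. The intervals cover counting error only.

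**Figure D1:**
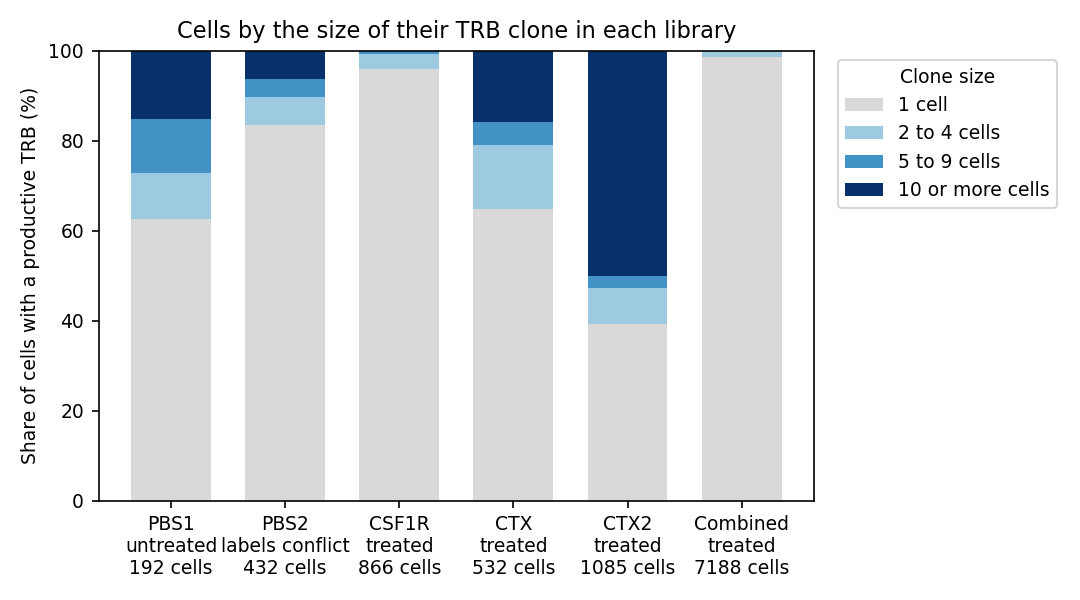
Share of cells with a productive TRB (y axis, %) by the size of their TRB clone, stacked for each of the 6 libraries (x axis, with the number of TRB cells), 1 bar per library. Clones of 10 or more cells took 50.0% of cells in CTX2 and none in CSF1R or Combined.

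The libraries differed in cell number, and the differences in expansion stayed when each was drawn down to 192 TRB cells, the number in PBS1. The expanded share was then 52.8% in CTX2, 27.8% in CTX, 13.6% in PBS2, 1.55% in CSF1R and 0.0563% in Combined. The 192 cells held 106 clones in CTX2, 133 in PBS1, 152 in CTX, 173 in PBS2, 190 in CSF1R and 192 in Combined. The inverse Simpson index, the number of equally sized clones that would give the same diversity, was 29.9 in CTX2, 46.9 in PBS1, 72.8 in CTX, 107 in PBS2, 188 in CSF1R and 192 in Combined. Over the treated libraries the expanded share averaged 25.4% ± 28.1 (SD, n = 4), and without CTX2 13.6%. The index averaged 121 ± 82.0 (SD, n = 4).

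The largest clone held 10.8% of TRB cells in CTX2 (exact 95% interval 9.0 to 12.8), 8.85% in PBS1, 7.71% in CTX, 6.25% in PBS2, 0.808% in CSF1R and 0.0835% in Combined. Over the treated libraries this averaged 4.85% ± 5.24 (SD, n = 4), and without CTX2 2.87%. In CTX2 the leading clone used TRBV4 with TRBJ2-7 and the CDR3 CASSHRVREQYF (117 cells). The next 2 used TRBV13-2, with the CDR3 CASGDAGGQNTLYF and TRBJ2-4 (86 cells) and with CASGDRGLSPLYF and TRBJ1-6 (59 cells). In CTX the leading clones were TRBV2 with TRBJ2-5, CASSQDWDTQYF (41 cells), TRBV19 with TRBJ2-5, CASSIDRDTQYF (18 cells), and TRBV13-1 with TRBJ2-7, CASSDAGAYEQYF (14 cells). In PBS1 they were TRBV14 with TRBJ2-4, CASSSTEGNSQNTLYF (17 cells), TRBV13-2 with TRBJ1-4, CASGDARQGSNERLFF (12 cells), and TRBV13-3 with TRBJ2-7, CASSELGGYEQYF (9 cells). In PBS2 they were TRBV13-2 with TRBJ2-5, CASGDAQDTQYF (27 cells), TRBV13-1 with TRBJ2-7, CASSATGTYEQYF (6 cells), and TRBV14 with TRBJ1-3, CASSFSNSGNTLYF (6 cells).

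The leading clones of the less expanded libraries were small. In CSF1R they were TRBV1 with TRBJ2-7, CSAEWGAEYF (7 cells), TRBV5 with TRBJ2-3, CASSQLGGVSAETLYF (3 cells), and TRBV1 with TRBJ2-5, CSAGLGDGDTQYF (3 cells). In Combined they were TRBV13-2 with TRBJ2-4, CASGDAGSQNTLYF (6 cells), TRBV12-1 with TRBJ2-3, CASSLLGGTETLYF (5 cells), and TRBV19 with TRBJ2-1, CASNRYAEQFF (4 cells). The alpha chain, which took no part in the definition of a clone, was shared by most cells of the large clones. Among cells with a TRA in clones of 10 or more cells, 93.4% in CTX2 carried their clone's main TRA (exact 95% interval 91.0 to 95.4), 93.5% in CTX, 96.4% in PBS1 and 95.8% in PBS2. The same TRA chains were found in 3.27%, 0.178%, 3.28% and 0.283% of the other cells of these libraries. Agreement was lower in the CTX clone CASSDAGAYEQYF, where 7 of 12 cells with a TRA carried its main TRA.

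No difference in clonal expansion between treated and untreated libraries was detectable, and the design could not have passed a threshold of 0.05. The treated mean of 25.4% was 12.1 percentage points below the 37.5% of PBS1 (treated minus untreated -12.1, two-sided exact permutation test, p = 0.8, n = 4 and 1). The treated libraries spanned 1.47% to 60.6%, a range that contains PBS1. The size of the difference depended on single libraries, since the treated mean was 13.6% without CTX2 and 33.3% without Combined. The largest clone share, the number of clones in drawn cells and the inverse Simpson index gave differences of -4.01, 27.0 and 73.8, each with an exact permutation p of 0.8 and an adjusted p of 0.8 over these 4 measures. With 4 libraries against 1, the smallest p possible is 0.2. With PBS2 counted as untreated the difference in expanded share was -1.61 points (exact permutation p = 0.933, n = 4 and 2, smallest possible 0.0667), and with PBS2 counted as treated it was -13.9 points (exact permutation p = 0.667, n = 5 and 1, smallest possible 0.167).

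Beta chain V gene use was led by the TRBV13 family, whose 3 members made up 33.9% ± 3.91 of clones (SD, n = 6). TRBV13-2 was used by 14.8% ± 1.76 of clones, TRBV13-1 by 11.1% ± 2.28, TRBV19 by 10.7% ± 1.77, TRBV5 by 9.26% ± 1.56 and TRBV13-3 by 8.06% ± 1.71 (SD, n = 6 each). TRBV1 followed with 7.19% ± 0.823, TRBV31 with 6.19% ± 1.64, TRBV4 with 5.71% ± 1.92 and TRBV20 with 5.69% ± 1.61 (SD, n = 6 each). Each clone was counted once, so expansion did not enter these shares. When each cell was counted once, TRBV13-2 was at 18.6% ± 7.67. TRBV13-2 lies on chromosome 6 at 41121396 to 41121832 in mm10, TRBV13-1 at 41116036 to 41116468 and TRBV13-3 at 41130147 to 41130585. TRBV31 lies at 41557693 to 41558371, downstream of the J genes, and joins by inversion.

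Among beta chain J genes, the TRBJ2 cluster was used by 62.4% ± 3.28 of clones and the TRBJ1 cluster by 37.6% ± 3.28 (SD, n = 6). TRBJ2-7 led with 15.6% ± 1.48, followed by TRBJ2-5 with 11.9% ± 1.90, TRBJ2-1 with 11.1% ± 2.14, TRBJ1-1 with 9.63% ± 1.13 and TRBJ2-3 with 9.62% ± 0.421 (SD, n = 6 each). TRBJ1-4 was used by 8.53% ± 1.12, TRBJ2-4 by 8.39% ± 0.682, TRBJ1-3 by 6.60% ± 1.06 and TRBJ2-2 by 5.65% ± 1.45 (SD, n = 6 each). No TRBV or TRBJ share was tested between treated and untreated libraries.

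Alpha chains spread over many V and J genes, and no gene reached 6% on average. The most used V genes were TRAV16N with 5.63% ± 1.84 of clones, TRAV6-6 with 5.36% ± 1.30, TRAV12D-2 with 4.28% ± 1.43, TRAV6-7-DV9 with 4.003% ± 1.19 and TRAV3-3 with 3.84% ± 1.53 (SD, n = 6 each). TRAV13-1, TRAV9D-1, TRAV9-4, TRAV8D-1 and TRAV14N-1 followed with means of 3.71%, 3.68%, 3.62%, 3.33% and 3.20%. The most used J genes were TRAJ52 with 4.75% ± 0.345, TRAJ56 with 4.22% ± 0.654, TRAJ45 with 4.21% ± 0.971, TRAJ22 with 4.15% ± 1.66 and TRAJ49 with 4.14% ± 0.685 (SD, n = 6 each). Mouse TRAV genes lie in near-identical duplicated blocks, and the reference genome comes from another strain than BALB/c, so the split between copies of a TRAV gene is uncertain.

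V genes that BALB/c mice are known to lose were rare among working beta chains and frequent among broken ones. Endogenous mammary tumour viruses of this strain encode superantigens that delete thymocytes with certain V segments, here TRBV12-1, TRBV12-2, TRBV15, TRBV16 and TRBV26. A nonproductive rearrangement makes no protein and so is not selected. These 5 genes made up 141 of 10174 distinct productive TRB rearrangements and 74 of 373 nonproductive ones. The log2 odds ratio of productive against nonproductive averaged -3.19 (SD 1.41, n = 6), lower in 6 of 6 libraries, with a two-sided exact sign-flip permutation p of 0.03125, the smallest that 6 libraries can give. It averaged -2.38 over the 4 libraries named by number alone and -4.81 over the 2 whose names start with JR, CTX2 and Combined.

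Tested library by library, the difference passed in 4 of 6. In Combined 1.01% of productive and 21.0% of nonproductive rearrangements used a listed gene, a log2 odds ratio of -4.71 (Fisher's exact test, p = 3.48e-47, adjusted over 6 libraries 2.09e-46). In CTX2 the shares were 3.11% and 50.0%, a log2 odds ratio of -4.92 (Fisher's exact test, p = 5.18e-08, adjusted 1.55e-07). CSF1R and PBS2 passed as well, with adjusted Fisher's exact p of 0.00709 and 0.0280, and PBS1 and CTX did not, with 0.0953 and 0.273. By gene, TRBV12-1 averaged 0.360% of productive and 5.99% of nonproductive rearrangements, TRBV15 0.549% and 8.58%, and TRBV26 0.218% and 4.25%. Without CTX2 the nonproductive means of TRBV15 and TRBV26 were 5.29% and 2.61%, and without PBS2 the productive mean of TRBV26 was 0.112%. For TRBV12-2 and TRBV16 the direction was not settled, each being higher among productive rearrangements in 3 of 6 libraries. TRBV12-2 averaged 0.592% and 0.527%, with a productive mean of 0.143% without PBS1 and a nonproductive mean of 0.156% without CSF1R, and TRBV16 averaged 1.33% and 1.83%, with a nonproductive mean of 0.943% without CTX2. Over the 6 libraries pooled, TRBV12-2 had 13 productive and 3 nonproductive rearrangements (0.128% and 0.804%) and TRBV16 had 71 and 8 (0.698% and 2.14%). Outside the list, and chosen after its values were seen, TRBV23 had 22 productive and 44 nonproductive rearrangements. Lower shares among productive rearrangements were not particular to the list: TRBV4 averaged 5.61% of productive and 16.0% of nonproductive rearrangements and TRBV31 6.01% and 13.3%, each lower among productive ones in 6 of 6 libraries.

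**Figure D2:**
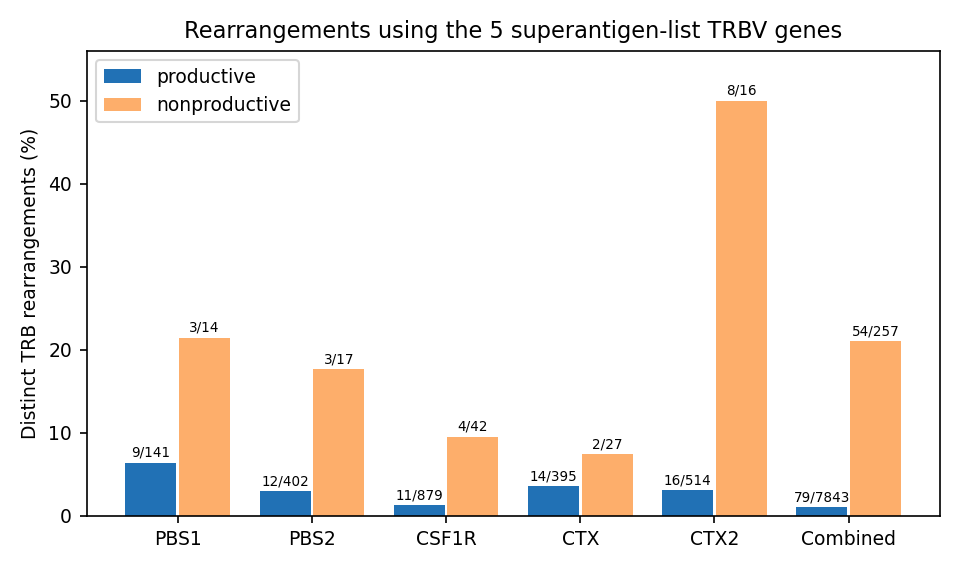
Share of distinct TRB rearrangements (y axis, %) that used 1 of the 5 listed TRBV genes, among productive (blue) and nonproductive (orange) rearrangements of each library (x axis), with the counts above the bars. The productive share was lower in 6 of 6 libraries; PBS1, PBS2 and CTX2 rest on 14, 17 and 16 nonproductive rearrangements.

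Invariant T cells were scarce. Natural killer T (NKT) cells, which recognise lipids on CD1d through a TRAV11-TRAJ18 alpha chain, made up 23 of 8974 cells with a TRA. Their share was 1.15% in CTX2 (12 cells, exact 95% interval 0.595 to 2.0), 0.794% in CTX (4 cells, 0.217 to 2.02) and 0.0824% in Combined (5 cells, 0.0268 to 0.192). PBS1 and PBS2 held 1 cell each, and CSF1R had 0 of 764 cells, which allows a share of up to 0.393%. Over the treated libraries the mean was 0.506% ± 0.557 (SD, n = 4), without CTX2 0.292%, and with each TRB clone counted once 0.918%. Of 22 NKT cells with a TRB, 15 used a usual NKT partner (TRBV13-1, TRBV13-2, TRBV13-3, TRBV29 or TRBV1), genes that 45.7% of all clones used. By library these were 6 of 11 in CTX2, 3 of 5 in Combined, 4 of 4 in CTX and 1 of 1 in PBS1 and in PBS2. The beta chains thus add little to the NKT call in CTX2, where 11 of the 12 cells carried the exact NKT alpha chain CDR3. In Combined 3 of the 5 cells carried it, in CTX 4 of 4, and in PBS1 and PBS2 1 of 1 each. Mucosal-associated invariant T (MAIT) cells, with TRAV1-TRAJ33, numbered 8 of 8974, at a treated mean of 0.162% ± 0.107 (SD, n = 4), or 0.266% with each TRB clone counted once.

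Expanded clones, taken as 2 or more cells with the same TRB, used the TRBV13 family more often than single-cell clones in each library, but the difference did not pass correction. The share was higher by 11.8 percentage points on average (SD 11.3, n = 6), in 6 of 6 libraries, with a two-sided exact sign-flip permutation p of 0.03125, the smallest possible, and an adjusted p of 0.156 over 5 measures. The unadjusted exact permutation p was 0.0938 with clones of 3 or more cells, 0.0938 with TRA and TRB together and 0.125 without possible doublets, at differences of 10.7 to 11.3 points. It was 53.8% against 27.5% in PBS1, 60.0% against 34.9% in PBS2 and 46.4% against 36.1% in CTX2, and 39.5% against 38.8% in CTX. The mean was 14.5 points over the 4 numbered libraries and 6.47 over the 2 JR libraries. In this comparison each clone counted once: shares of cells were averaged over clones, and UMIs were medians of clone medians. Median CDR3 length differed by -0.25 amino acids (SD 0.418, exact permutation p = 0.5, adjusted 0.5, n = 6), by -0.417 with TRA and TRB together or without possible doublets, and by -0.1 without Combined. The share of cells with 2 or more productive TRA differed by 2.91 points (SD 5.39, exact permutation p = 0.281, adjusted 0.469, n = 6) fell to 1.31 without CSF1R and turned to -0.434 with clones of 3 or more cells. Median TRB UMIs differed by 1.33 (SD 2.36, exact permutation p = 0.375, adjusted 0.469, n = 6), by 0.5 without CTX2, by 2.88 with TRA and TRB together and by 4 with clones of 3 or more cells. The share of cells with a productive TRA differed by 3.20 points (SD 4.01, exact permutation p = 0.156, adjusted 0.391, n = 6), by 2.06 without CTX2 and by 6.31 with clones of 3 or more cells.

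Clones were almost entirely private to a library. Of 9332 TRB clones by nucleotide sequence, 15 (0.161%) occurred in more than 1 library, and in none of them did a copy share a cell barcode with a copy in another library. The largest clone shared by its TRB was TRBV13-2 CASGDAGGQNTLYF, with 86 cells in CTX2 and 1 in Combined. Its alpha chains differed, TRAV7-1 with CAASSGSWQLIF in CTX2 and TRAV6-5 with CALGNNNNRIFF in Combined. Of 14 library pairs of shared clones with a TRA in both, 1 had the same TRA nucleotides. By amino acid sequence, 107 of 9105 CDR3 sequences (1.18%) were shared, 7 of them by 3 or more libraries. Without Combined, which holds most of the cells, 2 nucleotide clones and 20 amino acid sequences were shared. Shared CDR3 sequences were shorter than private ones by 0.70 amino acids on average (shared minus private -0.702, SD 0.340), in 6 of 6 libraries, with a two-sided exact sign-flip permutation p of 0.03125, the smallest possible. The 6 differences are not independent, since a shared sequence enters each library that holds it and Combined held 92 of the 107. With each distinct sequence counted once, a test chosen after the data were seen, 107 shared sequences averaged 13.1 amino acids and 8998 private ones 13.8, a difference of -0.717 (two-sided permutation p = 1e-05 over sequences, the smallest that 100000 permutations can give). The difference was -0.590 over the 4 numbered and -0.924 over the 2 JR libraries.

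When a cell carried a pair of TRA rearrangements, their J genes lay close together on the chromosome. TRAJ genes are numbered from the constant-region end of the locus, and rearrangement on both chromosomes proceeds from high to low numbers. Across 1654 cells, each clone counted once, the TRAJ numbers of both rearrangements were correlated within libraries (Spearman rho 0.550 weighted by cells, permutation p = 1e-05, the smallest that 100000 permutations can give). The coefficient was positive in 6 of 6 libraries: 0.779 in PBS1 (27 cells), 0.691 in PBS2, 0.681 in CSF1R, 0.643 in CTX, 0.559 in CTX2 and 0.514 in Combined (1222 cells), each with a permutation p of 1e-05 and an adjusted p of 1e-05. The median distance ran from 4 TRAJ numbers in PBS1 to 8 in PBS2 and Combined, against 14 to 16 when partners were shuffled. The correlation is across cells, which are not independent replicates of a mouse.

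**Figure D3:**
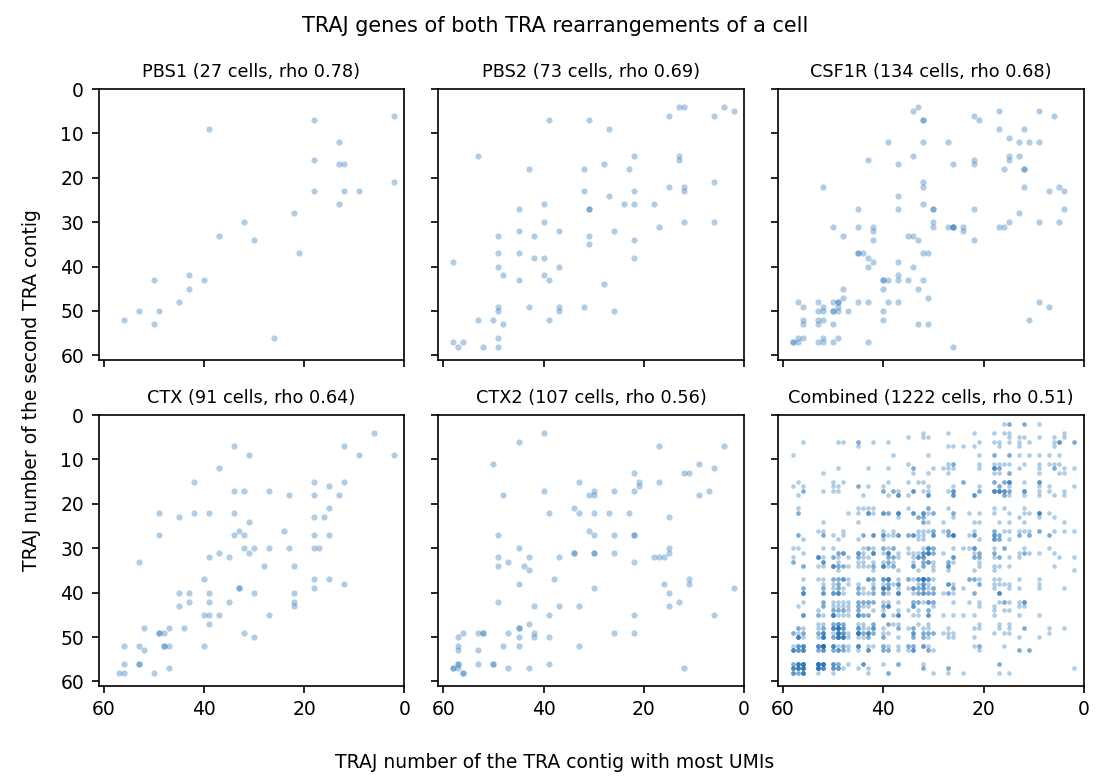
TRAJ number of the second TRA contig (y axis) against that of the TRA contig with most UMIs (x axis), both axes reversed, 1 panel per library and 1 point per cell, each clone once. Points gather along the diagonal in the 6 libraries, with Spearman rho from 0.514 in Combined to 0.779 in PBS1.

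V and J genes of the same alpha chain were joined with a weak preference for order along the locus. TRAV genes nearer to the J cluster were joined to J genes of higher number, and distant TRAV genes to J genes of lower number. Across 9888 distinct TRA rearrangements, Spearman's rho between the chromosome 14 position of the TRAV gene and the TRAJ number was 0.129 (weighted over libraries, permutation p = 1e-05, the smallest possible). The 2804 rearrangements with the most distant TRAV genes, starting at or before 52915915 in mm10, had a median TRAJ number of 33. The 2489 with the nearest, starting at or after 53545014, had a median of 40. Combined gave 7365 of the 9888 rearrangements, and by library these medians ran from 30.5 to 37 and from 26 to 42, so that the ranges overlapped. The coefficient was 0.162 in CTX2, 0.142 in CSF1R and 0.137 in Combined, with adjusted permutation p of 0.00022, 0.00012 and 6e-05. It was 0.0803 in CTX, 0.0597 in PBS2 and -0.0513 in PBS1, with adjusted permutation p of 0.130, 0.258 and 0.516 over 164 to 455 rearrangements. The correlation is across rearrangements, which are not independent replicates. The split between copies of a TRAV gene is uncertain, so the positions used here are uncertain too.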

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

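The checks below were fixed in kind before the data were examined, except the comparison of contigs and barcodes outside called cells, which was chosen after the table had been seen.

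In 50 measures of the 4 treated libraries, 3 had a library far from the other 3 by Dixon's test, and chance flags about 1 group in 20, or 2.5 of 50. CTX used TRBV13-3 in 10.97% of clones, against 6.75% to 7.45% in the other treated libraries, and TRAV13-1 in 5.82%, against 3.07% to 3.38%. Combined used TRAJ56 in 4.001% of clones, against 4.64% to 4.76% in the other treated libraries.

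For the order of V and J genes in alpha chains, the coefficient of the untreated library had the opposite sign to those of the treated libraries, but no order was detected in it. Spearman's rho between TRAV position and TRAJ number was -0.0513 in PBS1 (permutation p = 0.516 over 164 rearrangements) and 0.0803 to 0.162 in the 4 treated libraries. It was 0.0597 in PBS2 (permutation p = 0.215). The difference between treated and untreated libraries was not tested.

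Immunoglobulin contigs in barcodes that were not called as cells made up 1.38% of all contigs in CTX2 (75 contigs, exact 95% interval 1.09 to 1.73), against 0.151% in PBS1 (2 contigs, 0.0183 to 0.545). They were 0.600% of contigs in CTX, 0.464% in PBS2, 0.0470% in CSF1R and 0.0292% in Combined. Barcodes with contigs that were not called as cells made up 60.5% of barcodes in CTX (exact 95% interval 58.3 to 62.7), against 52.3% in PBS1, 54.5% in PBS2, 58.2% in CTX2, 28.0% in CSF1R and 14.6% in Combined.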

How the results depend on the processing

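Alternatives for PBS2, for TRA pairs with the same J gene, for NKT cells by their main TRA alone, for CDR3 length with each sequence once and for the index from pairs of cells were added after seeing the data. Of 153 alternative values of the main results, 139 kept their direction and side of the threshold or stayed within the spread. Part of this was fixed in advance. Leaving out 1 library cannot move a mean by its SD between libraries, so those values were bound to stay within the spread. In the comparison of expanded with single-cell clones, 5 libraries cannot pass, so leaving out a library could only change the direction. The count is therefore no measure of robustness. The expanded share averaged 20.5% to 26.2% over its alternatives and 13.6% to 33.3% without each treated library in turn. With at least 2 UMIs per contig, complete receptors were found in 58.6% of cells. Without drawing down, the inverse Simpson index averaged 1986, and 81128 when computed from pairs of cells drawn without replacement. The latter mean rested on Combined, with a value of 315001 that exceeded its 7188 TRB cells. The index was 34.4 in CTX2, 111 in CTX and 9364 in CSF1R. Counting cells in place of clones gave TRBV13-2 18.6%. Leaving out each library in turn gave superantigen log2 odds ratios of -3.55 to -2.84, where exact permutation of 5 libraries cannot pass (p = 0.0625, the smallest possible); the other alternatives gave -3.42 to -2.87. Shared nucleotide clones numbered 2 to 15 and shared amino acid sequences 20 to 97 without each library in turn, the lowest without Combined. The share of cells with 2 or more productive TRA in expanded minus single-cell clones turned to -0.434 points with clones of 3 or more cells and to -0.0273 with TRA and TRB together; the cause was not tested. NKT cells averaged 0.918% when each TRB clone was counted once. The TRAJ pair correlation was 0.511 without pairs sharing a J gene. No paired analysis was possible because only 1 untreated library was tied to a sample. Few nonproductive TRB rearrangements, 14 to 17, limit the precision in PBS1, CTX2 and PBS2.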

Other observations

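The tests in this part were chosen after the values had been seen, except the drawing down to 192 cells, which was planned before.

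Some of the 176 expanded clones with a TRA carried near-identical receptors on both chains in different libraries. Clones were matched when they differed in TRB nucleotides but had the same TRBV gene, TRB CDR3 sequences within 1 amino acid, the same TRAV family and TRAJ gene, and TRA CDR3 sequences within 1 amino acid. Across libraries 52 pairs of clones matched, 26 without CTX, 19 without CTX2 and 25 without Combined, and 9 when identical CDR3 sequences were required. Clones linked through a chain of matches were joined into a group, so clones of a group need not match each other. With matches within libraries included, there were 16 groups of clones, of which 12 spanned libraries and 5 held expanded clones in 2 or more libraries. The rest lay in PBS1 or PBS2 alone. In the TRBV20 group of PBS1 and the TRBV14 group held by PBS1 alone, a clone of 1 cell had the same TRA nucleotides as a clone of 7 and of 17 cells. The same held in PBS1 for a TRBV13-3 clone of 1 cell and the clone of 9 cells. In CTX it held for single-cell clones of TRBV13-1 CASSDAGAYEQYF and the clone of 14 cells. Sequencing errors were not checked within libraries and stay open for these clones. The largest group, TRBV13-2 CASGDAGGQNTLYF or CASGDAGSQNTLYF with TRAV7-1 and TRAJ22 (such as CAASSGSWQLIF), had 10 clones with 10 different TRB nucleotide sequences and 8 different TRA nucleotide sequences. It held 157 cells in 6 clones of CTX2, 3 cells of CTX and 8 cells in 3 clones of Combined, among them the largest clone of that library.

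The second group joined TRBV13-2 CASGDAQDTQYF, the largest clone of PBS2 (27 cells), to close variants in CTX (3 cells) and CTX2 (2 cells), each with TRAV12D-2, TRAJ39 and the TRA CDR3 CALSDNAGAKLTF. Its 3 clones had 1 TRA nucleotide sequence. The clones of PBS2 and CTX differed by 1 TRB nucleotide, so an error in a copy carried between these libraries stays open for that pair. The third was TRBV13-1 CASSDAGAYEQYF with TRAV14N-1 and TRAJ58, in PBS1 (4 cells), PBS2 (1 cell) and CTX (16 cells in 3 clones). The 3 CTX clones had the same TRA nucleotides, so sequencing errors within CTX stay open for its single-cell clones. In the CTX clone of 14 cells, 7 of the 12 cells with a TRA carried this alpha chain. The other 2 groups with expanded clones in several libraries were TRBV14 with TRAV12-1 and TRAJ45, in PBS1 (7 cells) and CTX2 (2 cells), and TRBV5 with TRAV10N or TRAV10D and TRAJ52, expanded in CTX (2 cells) and CTX2 (2 cells), with single-cell clones in PBS1 and CTX. The expanded TRBV5 clones, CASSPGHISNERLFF in CTX and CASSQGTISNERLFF in CTX2, did not match each other under the rule. They were joined only through single-cell clones. CSF1R held no expanded clone of any of the 16 groups.

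Among 22 pairs of expanded clones from different libraries with matching TRB, 17 also matched in TRA (77.3%), against 10 of 432 such pairs of single-cell clones (2.31%), a difference of 75.0 percentage points. Permuting TRA among the expanded clones of each library gave 0.121 matched pairs on average and 9 at most (permutation p = 1e-05, the smallest that 100000 permutations can give), which argues against chance pairing. Errors in copies of 1 clone carried between libraries would leave at most 1 changed nucleotide over both CDR3 sequences, and 5.88% of the 17 pairs (1 pair) were that close, the median being 4. The matching rule left out 17 pairs of clones with the same TRB nucleotides in different libraries; 3 lacked a TRA in a clone and could not be compared, and of the other 14, 1 had the same TRA nucleotides, TRBV1 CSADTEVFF in CTX2 (2 cells) and Combined (1 cell), and 1 differed by 1 TRA nucleotide, TRBV5 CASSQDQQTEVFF in CTX2 and Combined (1 cell each). The pairs are not independent: 13 belong to the largest group, and without it 4 of 9 matched; no biological explanation was tested, since the labels give no group that would test one.

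Clonal expansion differed widely between treated libraries, and cell number does not account for it, since drawn down to 192 cells CTX2 and Combined still differed by 52.7 percentage points. Free receptor RNA whose alpha and beta molecules reach droplets apart is argued against as the whole cause, since 93.4% of cells with a TRA in CTX2 clones of 10 or more cells and 93.5% in CTX carried their clone's main TRA, against 18.4% and 10.5% with TRA permuted among cells, a gap of at least 75.0 percentage points. Fragments of lysed cells that keep both chains stay open: median TRB UMIs in these clones against single-cell clones were 21 against 11 in CTX2 and 11 against 9 in PBS1, but 6 against 8 in CTX and 5 against 7 in PBS2, and barcodes outside cells were 52.3% to 60.5% in these 4 libraries, 28.0% in CSF1R and 14.6% in Combined. The libraries tagged CSF1R and Combined had expanded shares of 4.16% and 1.47% and the other 4, PBS included, 16.4% to 60.6%, where an exact permutation of the tags gave p = 0.133 (n = 2 and 4, smallest possible 0.0667), so a difference by tag may exist but cannot be told apart from a difference between single libraries. Differences in sorting or in the tissue taken are not recorded in the labels and stay open.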
